A study of Caenorhabditis elegans with 4 samples.

How the data were processed

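The series comprised 2 ChIP samples and 2 input samples from L3 hermaphrodites of 1 C. elegans strain with GFP-tagged JUN-1. Groups and replicate numbers were taken from the sample titles. The free-text descriptions do not match the titles, since those of the ChIP samples speak of input DNA and those of the input samples name the antibody. The titles, the source names and the attachment of the peak lists to the ChIP samples all give the same grouping, which was used.

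The deposited values were peak lists, 1 per ChIP replicate and 1 for the whole series named as combined. Peaks were called with PeakSeq, per the file headers and source column, on WormBase genome build WS180. The only value per peak was the q-value (a p-value adjusted by the peak caller), which the authors deposited in 2 places per peak, with equal values. The PeakSeq version, the aligner, the filters, the read depth, the use of the input samples as control and the way the combined list was made are not given in the sources used here. PeakSeq calls a region as enriched over a control, so list length and q-values depend on depth as well as on binding. The replicates were therefore compared by position, by rank and by share, and not by q-value as a measure of occupancy. The largest deposited q-value was 0.000112 in replicate 1 and 0.000299 in replicate 2 and in the combined list, so the lists do not end at 1 common threshold. In the replicate 2 list, 159 peaks were narrower than 200 bp and 28 narrower than 30 bp. The combined list held 157 and 28 such peaks, and in replicate 1 none was under 203 bp.

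Positions are those of the lists, 1-based, in WS180. Peak strength was ranked by q-value and is printed as −log10 q. No summits were given, so the midpoint of a peak stood for its position. Chromosome lengths of WS180 were not used here, so, other than planned, the span of a chromosome ran from base 1 to the last peak end in any list, in circular shifts as in densities. Overlap meant at least 1 bp. Circular shifts moved all peaks of a chromosome by 1 random offset, 100000 times, which keeps the number, width and spacing of the peaks. Permutations of medians by chromosome, of differing peaks over stretches of 1 Mb and of ranks within chromosomes numbered 10000, and other permutation tests used 100000. Shares carry 95% Wilson or exact (Clopper-Pearson) intervals. Fisher's exact test, exact binomial tests and permutation tests were used, and the odds ratio within groups of strength is the Mantel-Haenszel estimate, over the groups that held any overlapped peak. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used. The overlap count was tested on simulated data with 918 peaks. It gave the brute-force count at every offset tried, recovered 59.7% where 60% of overlaps had been planted, and gave p under 0.05 for 0 of 20 unrelated simulated lists. The unrelated peaks were placed evenly at random along each chromosome, so this does not cover lists that share regions of high peak density.

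The comparisons, the main settings, their alternatives and the rule for named regions were fixed before the data were examined, except where the text says otherwise. The rule names the 20 strongest combined peaks and the 5 strongest peaks of each replicate without a partner in the other. Replicate 1 had 0 such peaks. The planned tests of promoters, of AP-1 and CRE motifs and of gene lists needed a genome and annotation of the lists' build. The gene table at hand was of another assembly (WBcel235), and its coordinates were not set against WS180 positions. These tests were not run, and peaks are named by position alone, without genes. For the same reason jun-1, fos-1, unc-119 and kgb-1 have no value here.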

Results

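JUN-1 is the Caenorhabditis elegans member of the Jun family, basic leucine zipper factors that pair with Fos-type partners in the AP-1 complex. Its genomic binding was mapped by ChIP-seq, in which crosslinked chromatin is sheared, enriched with an antibody and sequenced. The worms were hermaphrodites at the third larval stage (L3), grown at 20 °C, of a strain that carries a transgene with the jun-1 locus (T24H10.7) fused to GFP, and chromatin was collected with a goat antibody against GFP. The series held 4 samples, namely 2 ChIP samples and 2 input samples of total chromatin. The values analysed were 3 peak lists in WormBase WS180 coordinates, 1 for each ChIP replicate and 1 combined list, each giving the q-value that the authors' peak caller assigned to a peak. The input samples had no values of their own here. Read numbers were not given in the sources used here, so the depth behind each list is unknown. Where an interval is printed for a share of peaks, it is a 95% interval that covers counting error only. Nothing in the labels says whether the replicates came from separate cultures, so p-values describe these lists and not a population of worms.

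The first question was where, and how strongly, tagged JUN-1 was detected. The combined list held 3467 peaks with a median width of 421 bp (quartiles 327 and 623 bp), which together covered 1996 kb, or 2.00% of the 99.8 Mb between the chromosome starts and the last peak of each chromosome. Its narrowest peak was 1 bp wide, and the 157 peaks under 200 bp are kept in all counts. Chromosome I carried the densest set, 46.2 peaks per Mb, followed by III with 39.9, IV with 36.3, X with 32.7, V with 29.1 and II with 27 per Mb. This order did not hold in replicate 1, where III was densest with 12 peaks per Mb, IV and X had 10.8 each, V had 7.89, I had 7.16 and II had 6.75. The fullest 1 Mb stretch lay between 9 and 10 Mb of chromosome I, with 77 peaks against a median of 33 per stretch. Of the combined peaks, 721 (20.8%) had another peak within 1000 bp.

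The strongest peaks lay mostly on X. Of the 20 strongest combined peaks, 13 (65.0%, exact interval 40.8 to 84.6%) were on X, against 16.2% of the remaining 3447 peaks (odds ratio 9.62, two-sided Fisher's exact test, p = 1.46e-06). This comparison was chosen after the values had been seen. The strongest peak of all was at X from 16929326 to 16931948, 2623 bp wide, with a −log10 q of 234. It ranked second in the replicate 1 list, with a −log10 q of 92.8. Other strong X peaks spanned 14525322 to 14526543 (−log10 q 165), 4208370 to 4209738 (153), 11093441 to 11094611 (153), 2996315 to 2997536 (152) and 8035853 to 8036975 (137). Further X peaks among the 20 strongest began at 1502870, 6296080, 12362656, 13700373, 16056022, 9465363 and 11790538. The 13 X peaks had a median width of 1171 bp and ranged from 816 to 2916 bp. Replicate 1 held a peak at each of the 20 regions, and 17 of the 20 were also among its own 20 strongest. In replicate 1, 15 of the 20 strongest peaks (75%) were on X, against 19.4% of its other peaks (Fisher's exact test, p = 1.84e-07).

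**Figure D1:**
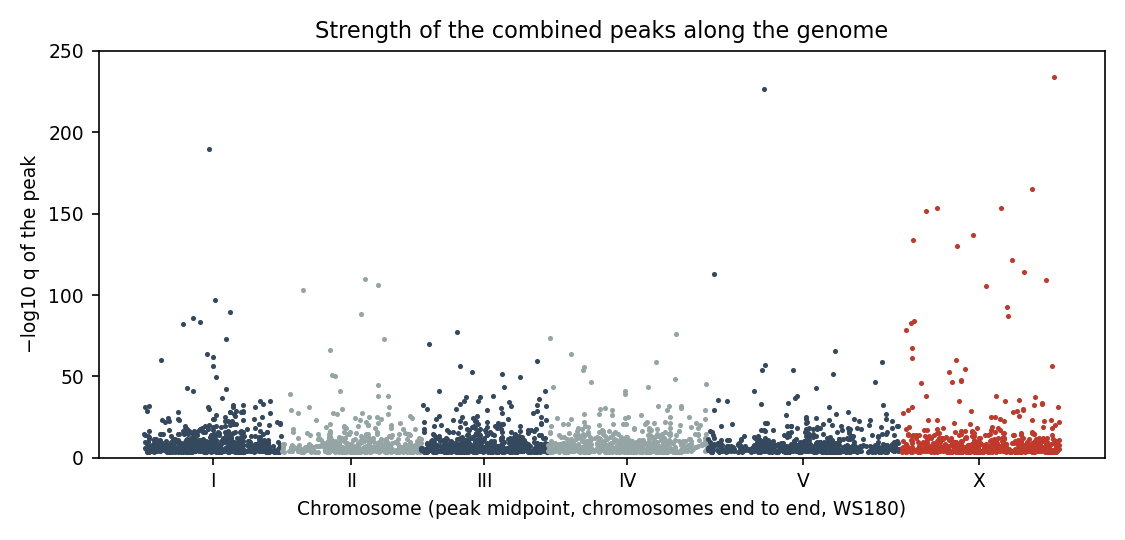
Each point is 1 of the 3467 combined peaks, placed by its midpoint along chromosomes I to V and X laid end to end (x axis, WS180) and by its −log10 q (y axis). Most peaks lie near the floor on every chromosome, and the X peaks (red) make up 13 of the 20 strongest.

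The 7 autosomal peaks among the 20 strongest had a median width of 6070 bp and ranged from 855 to 25340 bp. The strongest of these covered V from 6220745 to 6230080, with a −log10 q of 227, and was the strongest peak of replicate 1, where its −log10 q was 99.5. A peak at I from 7078766 to 7084835 had a −log10 q of 190 and ranked 14 in replicate 1. The others were at V from 723687 to 728436 (−log10 q 113), at II from 9108479 to 9133818 (110), at II from 10541817 to 10549624 (106), at II from 2378267 to 2379121 (103) and at I from 7656488 to 7660432 (96.8). The last of these ranked 154 in replicate 1.

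The widest peak was a continuous stretch of 25340 bp at II from 9108479 to 9133818, 2.71 times as wide as the next widest and 60.2 times the median peak. Replicate 1 covered the same stretch with 2 peaks, from 9108526 to 9123081 and from 9123287 to 9133254, separated by 205 bp. The outer edges in the replicate lists lay 47 bp apart at the low end and 564 bp apart at the high end. The replicate 1 parts had −log10 q values of 7.98 and 15.3, ranks 269 and 82, against a rank of 14 for the combined peak. The strain carries a transgene with the jun-1 locus, and reads from added copies of a locus align to that locus in the reference genome. At jun-1, reads can therefore come from added copies of the DNA as well as from binding. Whether this peak covers jun-1 was not analysed here. Chromosome II held 8 of the 20 widest combined peaks but 11.7% of the others (Fisher's exact test, two-sided, p = 0.00128, chosen after the values had been seen). Wide peaks on II also covered 10541817 to 10549624 (7.81 kb) and 8741788 to 8748271 (6.48 kb). The test treats peaks as independent and counts the 25340 bp stretch. Another of the 20 widest, at II from 10549879 to 10554154, lies directly beside the 7.81 kb peak. The excess on II is given for the combined list alone.

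**Figure D2:**
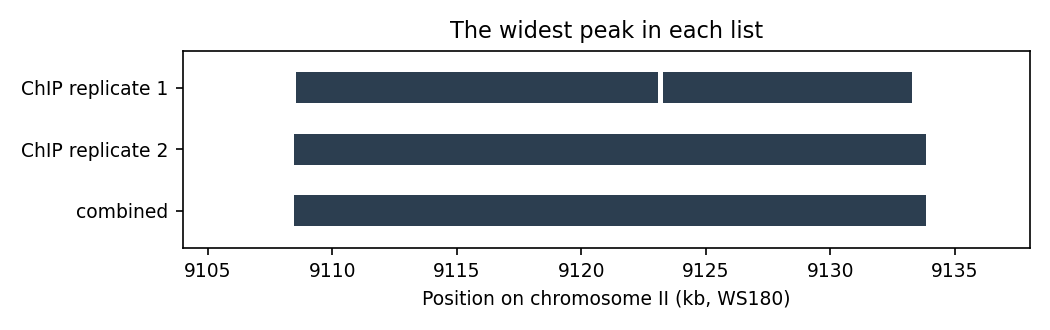
Bars are the peaks of each list over the widest stretch, drawn to scale against position on chromosome II (x axis, kb, WS180), with 1 row per list. The stretch is 1 peak in the replicate 2 and combined lists and 2 peaks, 205 bp apart, in replicate 1.

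The second question was how far the replicate lists overlapped. Replicate 1 gave 918 peaks and replicate 2 gave 3472. Every one of the 918 replicate 1 peaks overlapped a replicate 2 peak by at least 1 bp (100%, exact lower bound 99.6%), and 833 lay wholly inside their partner. In 100000 circular shifts of the replicate 1 peaks along their chromosomes, the mean overlap was 4.24% and the highest 25.2% (one-sided permutation p = 1e-05, the smallest the shifts can give). Offsets near 0, which leave a chromosome almost in place, were not excluded. The highest value can therefore hold true overlap and is not a measure of random placement. With a reciprocal overlap of at least 50%, 88.1% of the replicate 1 peaks still had a partner, and with midpoints within 100 bp 80.4% did. In the other direction, 891 of the 3472 replicate 2 peaks (25.7%, exact interval 24.2 to 27.1%) overlapped a replicate 1 peak, and 2581 did not. The overlapped replicate 2 peaks had a median width of 629 bp, against 376 bp for the rest. When the lists were restricted to their 918 strongest peaks each, 81.5% of the replicate 1 peaks had a partner.

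The replicate 2 peaks without a replicate 1 partner were mainly the weaker ones. When the replicate 2 list was cut by rank into 10 equal groups, 339 of 348 peaks (97.4%) were overlapped in the strongest group, and 76.9, 45.2, 23.9 and 9.22% in groups 2 to 5. None of the 347 peaks in either of the 2 weakest groups was overlapped (0%, exact upper bound 1.06% each). The strongest replicate 2 peak without a partner ranked 203, at II from 8015311 to 8017345, with a −log10 q of 24.7. The next 4 were all on chromosome I, at 7595406 to 7596093 (−log10 q 23.5), 10775773 to 10776817 (23.3), 14469150 to 14469499 (21.8) and 9869021 to 9869927 (20.9).

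Peaks found in both lists kept a similar order of strength. Over the 918 pairs, Spearman's rho between the −log10 q values was 0.79 and Pearson's r of their logarithms was 0.84 (two-sided permutation test with 100000 permutations, p = 1e-05 for each, the smallest possible). These are relations across peaks, which are not independent replicates. In addition, 25 replicate 2 peaks were the partner of more than 1 replicate 1 peak, so their values enter more than 1 pair. Within single chromosomes, rho ranged from 0.80 on IV to 0.87 on X. In all 918 pairs the q-value was smaller in replicate 2, and −log10 q there was a median of 2.42 times the replicate 1 value (quartiles 2.03 and 2.90). Replicate 2 peaks were wider in 890 of the pairs, with a median width ratio of 1.22, and the midpoints of a pair lay a median of 24 bp apart. A q-value grows smaller with sequencing depth at the same enrichment, so these ratios are not ratios of occupancy. The replicate 2 list nearly equals the combined list, as described further on, and whether it holds reads of replicate 1 cannot be told from the lists.

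**Figure D3:**
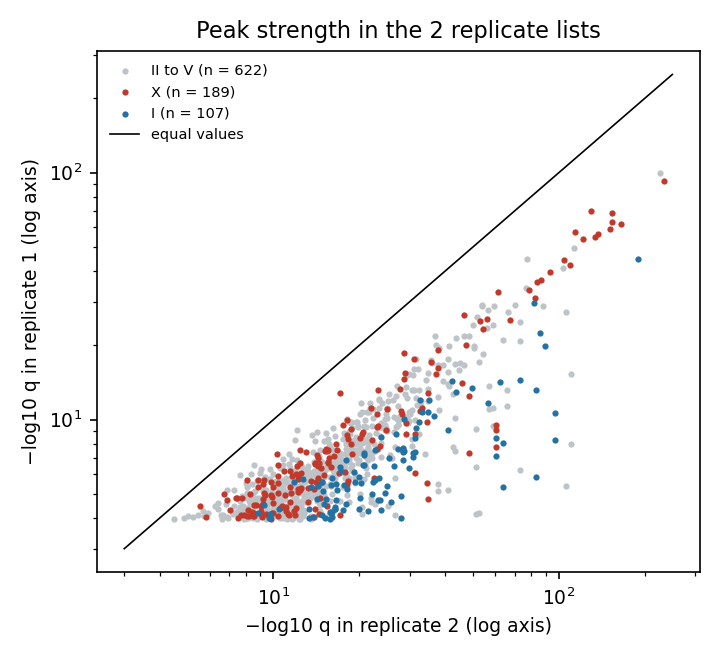
Each point is 1 of the 918 replicate 1 peaks, plotted by the −log10 q of its replicate 2 partner (x axis, log scale) and its own −log10 q (y axis, log scale), with the line of equal values in black. All points lie below the line, and the 107 peaks of chromosome I (blue) lie farther below it than most others.

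Chromosome I departed most from the other chromosomes in this comparison, and II also departed once strength was allowed for and I was left out. Replicate 1 overlapped 103 of the 691 replicate 2 peaks on I (14.9%, Wilson interval 12.4 to 17.8%), against 28.3% on the other chromosomes (odds ratio 0.44, Fisher's exact test, p = 4.82e-14, Benjamini-Hochberg adjusted over the 6 chromosomes 2.89e-13). On X the share was 31.8% against 24.4% elsewhere (Fisher's exact test, adjusted p = 0.000909). The shares on II (24.5%), III (29.3%), IV (28.9%) and V (26.2%) did not pass an adjusted p of 0.05 by the same exact test, which does not allow for peak strength. Within the 10 groups of replicate 2 strength, the pooled odds ratio for I was 0.067 (95% interval 0.042 to 0.107). Against all other chromosomes, I included, the ratio was 1.61 for III (95% interval 1.14 to 2.26), 2.2 for IV (1.59 to 3.04), 1.98 for V (1.42 to 2.76) and 1.98 for X (1.43 to 2.73), all above 1, and 0.82 for II (0.552 to 1.22). With I left out, the intervals for III, IV, V and X all included 1, and X (1.15, 0.823 to 1.60) did not stand apart from IV (1.28, 0.914 to 1.79) and V (1.22, 0.869 to 1.71). For II the ratio with I left out was 0.46 (0.298 to 0.697), an interval below 1. In group 2, 44.0% of the peaks on I were overlapped against 86% elsewhere, and in group 3, 7.14% against 57.4%. The comparisons by chromosome were chosen after the values had been seen. Where a pair existed, −log10 q in replicate 2 was a median of 3.66 times the replicate 1 value on I and 2.34 times on the other chromosomes. Chromosome I held 19.9% of the replicate 2 peaks and 11.7% of the replicate 1 peaks, against 15% of the covered span.

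**Figure D4:**
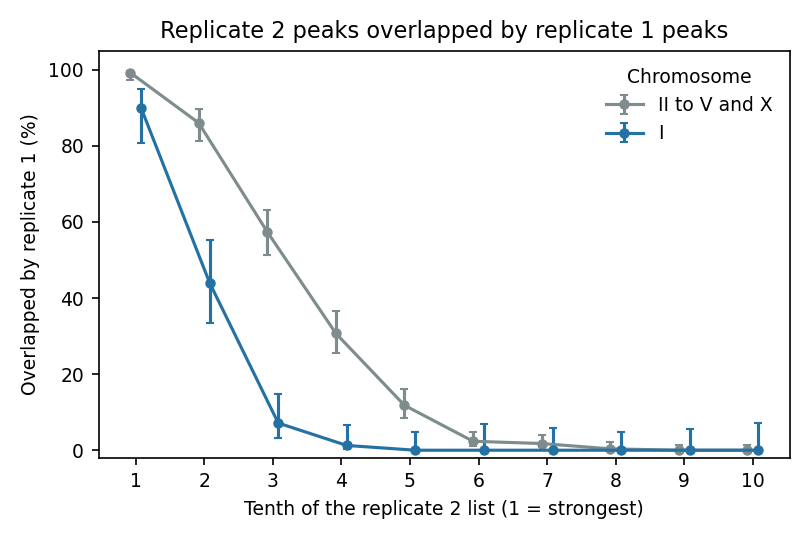
Share of replicate 2 peaks overlapped by at least 1 bp by a replicate 1 peak (y axis, %) in 10 equal groups of the replicate 2 list from strongest to weakest (x axis), for chromosome I (blue) and the other chromosomes (grey). Bars are 95% Wilson intervals. The share falls with strength in both sets, and earlier on I, where it is 44.0% in group 2 against 86% elsewhere.

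A further comparison set the combined list beside the replicate lists. Of the 3467 combined peaks, 891 (25.7%, Wilson interval 24.3 to 27.2%) overlapped peaks of both replicates, 2569 overlapped replicate 2 alone, 0 overlapped replicate 1 alone and 7 overlapped neither. The start, end and q-value of 3090 combined peaks (89.1%, Wilson interval 88.0 to 90.1%) were identical to those of a replicate 2 peak, and no combined peak had the start and end of a replicate 1 peak. Of 102 stretches of 1 Mb with peaks, 90 were identical in the combined and replicate 2 lists. All 377 differing combined peaks lay in the other 12 stretches, where only 5 of 382 combined peaks were identical to a replicate 2 peak. Of these 12 stretches, 6 were on X and 0 on III. Because of this identity, the 2 lists are not counted as separate evidence here.

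**Figure D5:**
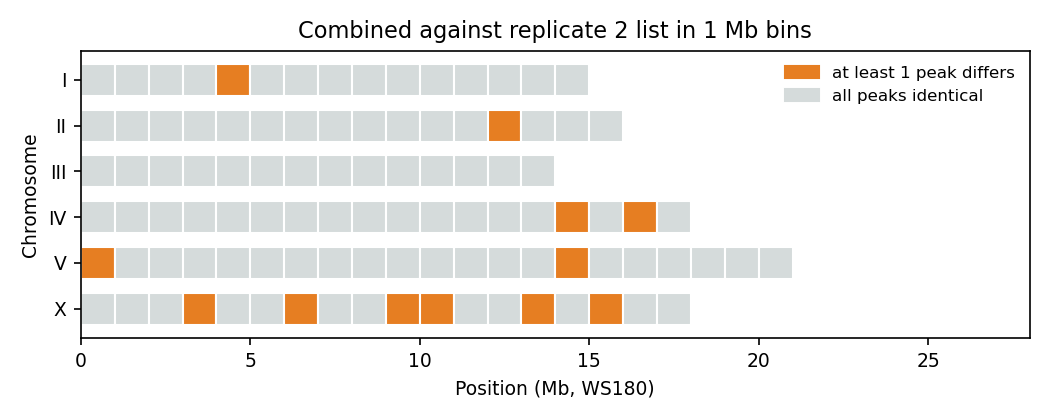
Each block is a 1 Mb stretch with peaks, placed by position (x axis, Mb, WS180) and chromosome (y axis). Grey blocks hold combined peaks that are all identical to replicate 2 peaks, and the 12 orange blocks hold all 377 combined peaks that differ.

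Peaks were more frequent in the middle of the autosomes. With each chromosome cut into 3 equal parts, the middle parts of the 5 autosomes held 1260 of 2896 autosomal combined peaks (43.5%, Wilson interval 41.7 to 45.3%), against a mean of 33.3% and a central 95% range of 27 to 40% in 100000 circular shifts (two-sided permutation p = 3.0e-04). By chromosome, the middle part held 47.5% of the peaks on V, 46.8% on II, 43.8% on I, 42.4% on IV and 37.5% on III. On X it held 36.1%. Replicate 1 alone gave 44.3% over the autosomes (two-sided permutation p = 9.4e-04). The parts were cut by length alone. Arms and centres of the autosomes differ in gene content, which was not allowed for, so no preference of JUN-1 for the centres follows.

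By number, X was not distinguished from the autosomes in the combined list. It held 571 combined peaks (16.5%, Wilson interval 15.3 to 17.7%), against 17.5% of the covered span (two-sided exact binomial test, p = 0.113). In replicate 1, X held 189 of 918 peaks (20.6%, Wilson interval 18.1 to 23.3%), above its share of the span (exact binomial test, p = 0.0168). In the same list IV also held 189 peaks on 17.5% of the span, III held 18% of the peaks on 13.8% of the span, and I held 11.7% on 15%, so the excess was not particular to X. The side on which X fell depended on the list. The binomial test treats peaks as independent, which neighbouring peaks are not.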

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

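Alternatives marked here as added, and all those by chromosome and for the strongest peaks on X, were chosen after seeing the data. Overlap of the replicates, the share of peaks in the middle part of the autosomes, the deficit on chromosome I and the excess of X among the strongest peaks kept their direction and their side of the threshold under every alternative run for them. The share of combined peaks overlapped by both replicates moved from 25.7% to 23.3% with a reciprocal overlap of 50% and to 50.7% in the stronger 50% of the list, which holds fewer weak peaks. The share of peaks on X turned from below to above its 17.5% of the span in the 891 combined peaks overlapped by both replicates (20.5%) and, added, in the 100 strongest combined peaks (30%). In the stronger 50% of the combined list it was also above, at 17.6%, a difference that did not pass the exact binomial test (p = 0.924). Leaving out each replicate in turn gave 16.6% on X without replicate 1 and 20.6% without replicate 2, and the latter also turned the direction. Because 0 combined peaks overlapped replicate 1 alone, the 891 peaks are all the combined peaks that overlap replicate 1. They largely restate the replicate 1 list and are not separate evidence from it. The 100 strongest peaks include the 20 strongest, where the excess of X had already been seen. The cause of these turns was not tested. Without replicate 1 or replicate 2, the share in the middle part ranged from 43.5 to 44.3%, and the share of the 20 strongest peaks on X from 65.0 to 75%. The size of the X excess depended on the number taken: X held 40% of the 50 strongest combined peaks (odds ratio 3.47) and 30% of the 100 strongest (odds ratio 2.24), against 65.0% of the 20 strongest (odds ratio 9.62). The values without replicate 1 come from the replicate 2 list, which nearly equals the combined list, so only those without replicate 2 test these results. Using the nearest in place of the strongest partner changed 0 pairs, because each replicate 1 peak had a single partner, so that alternative tested nothing. With replicate 2 restricted to the largest q-value of replicate 1 (added), 3081 of its peaks remained and 100% of replicate 1 peaks kept a partner. No second score column, gene share of X or WS180 annotation was used here, so the alternatives that need them were not run, nor were those of the promoter, motif and gene list tests. No paired analysis was possible because the input samples, which share replicate numbers with the ChIP samples, had no values here. Unknown depth limits any statement about the 2581 replicate 2 peaks without a partner to non-detection in replicate 1.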

Other observations

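The tests in this part were chosen after the results were seen, except 3. These were the odds ratio within groups of strength, the shares in 3 parts of chromosome I and the median strength on X. For the last, no list was named beforehand. The patterns these 3 tests address had themselves been picked from the data. The 10 strongest X peaks were the same regions in the combined and replicate 1 lists, and at this number they were spread along the chromosome. Their midpoints lay a mean of 1.71 Mb apart, with a smallest gap of 0.825 Mb, whereas 10 X peaks drawn at random from the combined list had a median smallest gap of 0.115 Mb (one-sided permutation p = 0.0032). In the replicate 1 list the smallest gap was also 0.825 Mb (one-sided permutation p = 0.00329). This held for the 13 strongest X peaks of the combined list (smallest gap 0.571 Mb, permutation p = 0.00133) but not for the 15 strongest (0.123 Mb, permutation p = 0.178), the 20 strongest (0.0425 Mb, permutation p = 0.308) or the 5 strongest (1.21 Mb, permutation p = 0.189). In replicate 1 it held for the 13 strongest (permutation p = 0.00115) and the 5 strongest (2.09 Mb, permutation p = 0.0377). It did not hold there for the 15 or 20 strongest (permutation p = 0.181 and 0.227). The gene table for WBcel235 places jun-1, the tagged gene, on chromosome II, which also holds the 25.3 kb peak. This was looked up after the width of the peak was seen, and a shared chromosome decides nothing about the peak. Whether that peak covers jun-1 was not analysed here, since the table and the lists use different assemblies, so added copies of the locus on the transgene and binding are not separated for it.

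The near identity of the combined and replicate 2 lists is the first pattern to follow up. A combined list called on pooled reads beside a replicate 2 list called on replicate 2 reads alone is argued against by the 89.1% of combined peaks with identical position and q-value, since added reads would change the q-values. The differences filled 12 stretches of 1 Mb, against at least 86 in 10000 permutations of the differences over the peaks, which is consistent with both lists being called on one set of reads with thresholds drawn anew for some stretches. Which reads these were stays open: the list named for replicate 2 could itself hold pooled reads of both replicates, because 0 of 918 replicate 1 peaks had a smaller q-value than their partner, as either a pool or a deeper library would give. If it were a pool, the overlap of the replicate lists would not compare independent samples.

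The deficit on chromosome I is the second. Weaker peaks on I in replicate 2 are argued against by the odds ratio of 0.067 within groups of equal strength, and the median −log10 q on I in replicate 2 was above that of the other chromosomes (7.20 against 6.35, permutation p = 9.0e-04), while in replicate 1 it was 5.78 against 6.00 (permutation p = 0.504). A difference in scaling that covered the whole chromosome in one replicate, for example against its control, may account for it: the overlapped share was 11.9, 18.2 and 12.8% in the 3 equal parts of I, and the highest upper bound, 22.9%, stayed below the 28.3% of the other chromosomes. Any cause that acts along the whole of I would give this too, so these shares do not single out scaling. In strength the departure was detected in the replicate 2 list, with 691 peaks on I, and not in replicate 1, with 107. A chromosome scaled down also loses weak peaks at the threshold, so these medians cannot show which list departed. In number I lay above its 15% of the span in replicate 2 (19.9% of the peaks) and below it in replicate 1 (11.7%). Which replicate carried the difference stays open, and no biological explanation was tested. A smaller deficit on II within groups of strength (odds ratio 0.46 with I left out) was not weighed.

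For the excess of X among the strongest peaks, a scaling that raised all X peaks may be part of the cause. The criterion set beforehand, a difference of at least 2 SD of the permuted one, named no list. It was met in the combined list, where the median −log10 q on X exceeded that of other peaks by 0.549 (SD 0.270, 10000 permutations, permutation p = 0.0376, Benjamini-Hochberg adjusted over the 6 chromosomes 0.0752). However, chromosome I, with 2 of the 20 strongest peaks, exceeded the others by 0.849 (permutation p = 9.0e-04, adjusted 0.0054). Looked at afterwards, the criterion was not met in replicate 1, with a difference on X of 0.296 (SD 0.265, permutation p = 0.244). Nor was it met in replicate 2, with 0.443 (SD 0.267, permutation p = 0.0917). The combined and replicate 2 lists are nearly the same, so the pass in one and the miss in the other are not separate results. They show that the value lay close to the criterion. A stricter demand that all 3 lists pass, tried only once these results were known, was thus not met, so the evidence for this part is weak. After −log10 q on X was divided by 1.09, the ratio of the medians, 12 of the 20 strongest combined peaks were still on X (Fisher's exact test, p = 1.25e-05). This correction takes the scaling as 1 factor. It cannot decide whether scaling was the whole cause, because a raised chromosome also gains weak peaks at the threshold, which holds its median down. Between the replicates, −log10 q of paired peaks differed by a median of 2.42 times, while the medians of the lists were 6.51 and 5.99. In number, however, X held 16.5% of the combined peaks on 17.5% of the span, so no gain of peaks on X was seen there. In replicate 1 it held 20.6%. The number that X would hold without scaling is not known, so these shares do not decide the question either. One hypothesis is that the strongest X peaks are separate sites, such as loading sites of the dosage compensation machinery, which acts on X in hermaphrodites. The gaps between the 10 strongest X peaks varied less than those of random X peaks (coefficient of variation 0.405 against a median of 0.887, one-sided permutation p = 0.00375). In the combined list this also held with the 8, 13 and 15 strongest (permutation p = 0.00687, 0.00013 and 0.00897). It was not so with the 20 strongest (0.793 against 0.938, permutation p = 0.182), nor with the 5 or 30 strongest (permutation p = 0.348 and 0.102). The evenness thus depends on the number taken. No list of such sites and no ChIP of an untagged strain was analysed here, so specific binding of JUN-1 and general recovery of these sites cannot be told apart.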
